A study of Homo sapiens with 49 samples.

How the data were processed

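RNA sequencing of 2 human neuroblastoma models was analysed: SHEP-21N cells with TET-off MYCN (20 libraries) and BE(2)-C cells with a TET-on hairpin against TWIST1 (18 libraries). Per the labels' protocols, cell number was determined before RNA isolation, ERCC spike-in RNA was added at lysis, polyadenylated RNA was selected and stranded libraries were made. Reads were aligned with HISAT to hg19 and FPKM were computed with Cufflinks 2.0.0, per the submitters' processing notes. The authors deposited 2 FPKM tables per experiment, 1 unnormalised and 1 rescaled to the spike-ins; how the rescaling was done is not given in the sources used here. Each table holds 23713 entries, 92 of them spike-ins. Of 49 listed samples 11 have no column in these tables (BE(2)-C with DMSO, or with JQ1 at 1 µM for 4, 8 or 24 h) and are not analysed here. Columns were matched to groups by their names; the number at the end of a name is used only to tell libraries apart. The SHEP-21N 0 h group has 2 libraries, numbered 1 and 2, and every other group has 3.

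Of the unnormalised values, 30.9% (SHEP-21N) and 33.8% (BE(2)-C) are 0 and the smallest value above 0 is 0.01; those listed at 0 stand at 0.0706 to 0.127 and at 0.0377 to 0.201 FPKM in the rescaled tables, so values near 0.1 there are no evidence of expression. FPKM give no read number, so the depth per library and its counting error are unknown; the spread between replicates stands in for both. Pearson's r of log2 values across genes was 0.951 to 0.981 between replicates, a description of the libraries and not a test. Spike-in totals in the rescaled tables ran from 32692 to 34903 and from 33930 to 36589 FPKM, and in the unnormalised tables from 26061 to 47480 and from 15455 to 140361.

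What was computed here used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with a mean of at least 1 FPKM in the unnormalised table of the experiment were tested, spike-ins left out: 11867 and 11433. A linear model with 1 mean per time point was fitted to log2(rescaled FPKM + 1) in limma with moderated variances and an intensity trend, each time was compared with 0 h or no doxycycline, and adjusted p is the Benjamini and Hochberg value over all tested genes. A gene changed where adjusted p was under 0.05. The median change of all genes was compared between library medians by an exact permutation test, two-sided. All comparisons of 1 experiment share its control libraries. On simulated data with known changes, the model recovered 19.4%, 83.6% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale for SHEP-21N at 24 h and 3.0%, 22.4% and 98.5% for BE(2)-C at 48 h, with 0.04% and 0.10% false calls. Simulated genes were independent, unlike genes of these libraries on the spike-in scale, so the shares of false calls may not carry over to the real data. The shares recovered may not carry over either. Few simulated genes were changed, and an adjusted p under 0.05 is easier to reach where many genes change, as at these times.

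Gene lists, 26 in all, were fixed and tested with camera (inter-gene correlation 0.01), with camera and a correlation estimated from the data, and with fry, with p adjusted over lists. A call for a list is an adjusted p under 0.05 from camera at 0.01, unless another test is named. On the spike-in scale the estimated correlations were 0.524 to 0.966 over lists in SHEP-21N cells at 24 h and 0.675 to 0.99 in BE(2)-C cells at 48 h. No list passed with them there (adjusted p of 0.923 or more and 0.956 or more). A call lost that way at those times therefore says little about the list. Camera compares a list with the other genes and fry with no change, so that fry gave the lower direction for cholesterol synthesis at 24 h in SHEP-21N cells where camera gave the higher. Lists of fewer than 3 tested genes were not tested: those for mitochondrially encoded, Schwann or glial, and blood genes in both models, and the epithelial list in BE(2)-C cells, where S100B, HBB and KRT19 were the 1 tested gene of the last 3. In 21 of 452 comparisons of a list between settings its direction turned with no call on either side.

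Named genes were chosen by a rule: at the latest time, the targeted gene, and the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05 whose libraries all lie beyond every control library (by chance 10% of genes do so for 3 against 3), leaving out spike-ins, small and uncharacterised RNAs (symbols starting MIR, SNOR, SCARNA, RNU, RNY, RNA5, RN7, RPPH, RMRP, VTRNA, LOC, LINC or FLJ, or holding -AS, -IT or orf); up to 4 members per list with the smallest adjusted p; and 3 rises and 3 falls at each earlier time. A few members that the rule names are not reported here. At 24 h in SHEP-21N cells 705 rises and 3639 falls were eligible, and at 48 h in BE(2)-C cells 8403 falls and no rise. The rule, tests, lists and alternatives were set before the data were examined, except where the text says otherwise.

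The alternatives were unnormalised values, centring each library on its median, a pseudocount of 0.1, no expression filter, leaving out each library in turn (on rescaled values only), 2 h as the reference for SHEP-21N at 24 h, and no intensity trend at the latest times. For sequences in 3′ UTRs, GENCODE release 29 on GRCh38 was used for sequence only, since the deposited values rest on hg19; 10071 of the 11433 tested genes (88.1%) were searched.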

Results

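RNA was measured in 2 human neuroblastoma cell models. SHEP-21N cells carry MYCN under TET-off control, so that doxycycline (0.2 µg/ml) shuts the gene down; 2 libraries at 0 h and 3 each at 2, 4, 6, 8, 16 and 24 h were compared. BE(2)-C cells carry a TET-on hairpin against TWIST1, induced with doxycycline (0.5 µg/ml); 3 libraries without doxycycline and 3 each at 3, 6, 12, 24 and 48 h were compared. Values are FPKM rescaled to ERCC spike-in RNA unless called unnormalised, means are given ± SD, and log2 fold changes were taken after adding 1 FPKM, which understates changes of weakly expressed genes. No label states that replicates came from separate cultures, so the spread behind each p-value is that between these libraries. No group with doxycycline but without the shutdown or the hairpin was analysed here. In SHEP-21N cells the labels give 8, 16 and 24 h index sequences also used at 0, 2 and 4 h. Libraries that share an index cannot be told apart in 1 sequencing pool. No label names the pools, so a difference between pools cannot be told apart from time when 8, 16 or 24 h is compared with 0 h.

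MYCN RNA fell within 2 h of doxycycline in SHEP-21N cells and stayed low to 24 h. It stood at 723 and 855 FPKM in the 2 libraries at 0 h, and all 18 later libraries lay between 9.46 and 188 FPKM. The mean went from 789 ± 93.4 FPKM (n = 2) to 159 ± 25.1 at 2 h (n = 3; log2 fold change -2.31, adjusted p = 1.18e-05). It was 32.0 ± 7.20 at 4 h and 14.1 ± 3.05 at 24 h (-5.72, SE 0.218, adjusted p = 3.24e-12). On unnormalised values it went from 728 ± 19.6 to 15.5 ± 0.117 FPKM (-5.46). MYC, the paralog of MYCN, rose from 2.51 ± 0.244 FPKM to 5.48 ± 0.205 at 6 h (+0.88, adjusted p = 0.00938). It stood at 10.3 ± 2.33 at 16 h (+1.67, adjusted p = 4.2e-05) and 5.47 ± 1.06 at 24 h (+0.87, adjusted p = 0.00204), and did not pass at 2 h or 4 h.

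**Figure D1:**
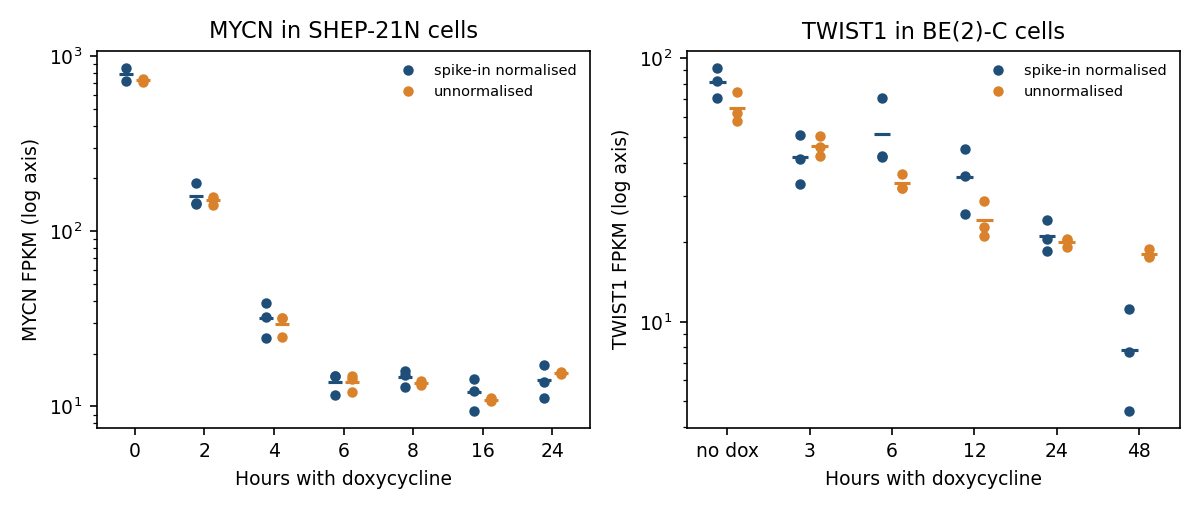
MYCN RNA in SHEP-21N cells and TWIST1 RNA in BE(2)-C hairpin cells in FPKM (logarithmic axis) against hours with doxycycline. Each point is 1 library, blue for spike-in-normalised and orange for unnormalised values, and bars are group means.

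After 24 h of MYCN shutdown in SHEP-21N cells, IGFBP5, EPGN and CXCL12 showed the largest rises, and FOSL1, CD3EAP and ECE2 were among the largest falls. The largest rise was that of IGFBP5, which encodes an insulin-like growth factor binding protein (3.51 ± 0.226 to 15.5 ± 2.16 FPKM; log2 fold change +1.87, SE 0.160, adjusted p = 1.09e-06). EPGN, an EGF receptor ligand (5.82 to 24.0 ± 4.76, +1.85, adjusted p = 3.82e-06), and the chemokine CXCL12 (1.78 ± 0.376 to 8.97 ± 2.40, +1.82, adjusted p = 1.26e-05) followed. DHRS3, a retinaldehyde reductase (11.1 to 39.9 ± 11.2, +1.73), ARHGAP29 (+1.60) and the secreted protein LRRC17 (59.9 ± 1.98 to 171 ± 27.6, +1.49) rose. The potassium channel KCNMA1 (+1.45), the forkhead factor FOXS1 (+1.43), the cell-surface protein CD109 (+1.33) and YPEL5 (+1.33) also rose. After MYCN itself, the largest fall that the naming rule gives among genes with 1 clear locus was that of FOSL1, an AP-1 subunit (129 ± 16.6 to 27.8 ± 5.36, -2.18, SE 0.236, adjusted p = 1.83e-05). Next came the RNA polymerase I subunit CD3EAP (28.8 to 6.41, -2.01, adjusted p = 1.09e-06) and the endothelin-converting enzyme ECE2 (42.6 to 10.4, -1.98). The U3 snoRNP protein RRP9 (132 ± 20.9 to 35.3 ± 9.04, -1.90, adjusted p = 4.52e-05), cyclin D1, CCND1 (57.3 to 15.3, -1.85, adjusted p = 1.2e-05), and the lipid transporter MFSD2A (11.8 to 2.60, -1.84) also fell. On unnormalised values IGFBP5 rose by 2.17 and CXCL12 by 2.13, while FOSL1 fell by 1.91 and RRP9 fell by 1.63. The naming rule also gives SNAR-C3 and SNAR-C4, near-identical copies at 21.4 and 20.4 FPKM at 0 h and listed at 0 in the unnormalised values at 24 h; each lost its call without any of 4 of the 5 libraries compared. MYCNOS (0.193 FPKM at 24 h) overlaps MYCN on the other strand, and reads of these 3 cannot be assigned with certainty.

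At 24 h, 731 of 11867 tested genes were higher and 3848 lower (16.0% of changed genes higher, 5856 at an unadjusted p under 0.05). The median gene fell by 0.31 on the log2 scale. Library medians of log2(FPKM + 1) were 3.51 ± 0.270 (n = 3) against 3.81 ± 0.088 (n = 2; exact permutation p = 0.3, two-sided, the smallest possible being 0.1). On unnormalised values, where the median moved by -0.04, 3430 were higher and 4324 lower (44.2% higher), and after centring on the median 3515 and 3823 (47.9%). Leaving out the 0 h library numbered 2 leaves 876 changed genes, and leaving out the 24 h library numbered 2 leaves 2779. The median shift was -0.173 without the 24 h library numbered 2, and -0.442 without number 0. Of the genes named at 24 h in the next paragraphs, RPL18, RPS28, COX5A, NELFA, DHCR7, STARD4, LAMP2, MAP1B, MAX, IFIT1, OAS3 and FOSL2 did not pass without the 0 h library numbered 2. Their adjusted p ran from 0.0581 (MAX) to 0.274 (STARD4). IRF9 did not pass without number 1 (adjusted p = 0.0506), OAS3 without the 24 h library numbered 2 (adjusted p = 0.0833) and STARD4 without number 0 (adjusted p = 0.0675).

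Most tested genes of ribosome production, nucleotide synthesis and the immediate early response fell at 24 h. Of 30 tested genes of ribosome biogenesis, 26 fell and 4 did not pass (27 fell when adjusted over the list alone), with the list median at -0.63 against that of all genes. Among them were RRP9, the ribosome assembly factor RRS1 (82.6 to 30.7 FPKM, -1.43), RRP12, which acts in export of ribosomal subunits (70.4 to 26.5, -1.39), and PPAN (79.9 to 30.4, -1.39). Camera called the list lower (adjusted p = 6.34e-07; adjusted p = 0.923 with an estimated correlation). On unnormalised values it kept its call (25 of 30 lower, adjusted p = 0.0179 with an estimated correlation). After centring 25 were lower too and camera called the list (adjusted p = 1.28e-09), but not with an estimated correlation (adjusted p = 0.237). Nucleotide, polyamine and one-carbon genes went the same way (22 of 26 lower; median -0.55 against all genes, adjusted p = 4.59e-05). Lower were spermidine synthase SRM (353 to 116, -1.62), the pyrimidine enzymes DHODH (-1.30) and CAD (68.1 to 27.8, -1.28), and the serine enzyme PSAT1 (-1.23). Cytoplasmic ribosomal proteins fell as well (21 of 30, -0.41, adjusted p = 0.00298), among them RPL18 (1503 to 754, -1.02) and RPS28 (3371 to 1845, -0.91). All 19 tested immediate early genes fell (-0.80, adjusted p = 2.78e-08), including the transcription factors EGR1 (4.75 to 1.12, -1.44) and NR4A1 (9.75 to 3.33, -1.32) and the phosphatase DUSP4 (2.33 to 0.457, -1.19). The calls of these 3 lists were lost at adjusted p = 0.923 with an estimated correlation, with which no list passed on this scale. On unnormalised values camera called all 3 lower (adjusted p = 8.38e-08 for nucleotide genes, 9.61e-08 for immediate early genes and 7.38e-06 for ribosomal proteins). With an estimated correlation those calls were lost too (adjusted p = 0.164 for nucleotide and immediate early genes and 0.472 for ribosomal proteins).

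Against that fall, interferon-response and mesenchymal genes stood above the other genes at 24 h. Of 16 tested interferon-response genes 3 rose, IFI44 (1.04 to 2.96 FPKM, +0.95, adjusted p = 0.00012), the STAT partner IRF9 (3.78 to 7.54, +0.82) and IFIT1 (0.725 to 1.58, +0.57), and 12 did not pass. OAS3 fell (5.96 to 3.86, -0.52). The list median lay 0.45 above that of all genes (0.453, camera adjusted p = 8.99e-04; adjusted p = 0.923 with an estimated correlation). On unnormalised values 12 rose and 1 fell (adjusted p = 0.0179 with an estimated correlation). After centring 12 rose and 1 fell too and camera called the list (adjusted p = 0.00101), but not with an estimated correlation (adjusted p = 0.121). Of 29 tested mesenchymal identity genes 5 rose, such as the galectin LGALS1 (545 to 1196, +1.10) and the collagen COL5A2 (56.8 to 99.6, +0.79). Another 3 fell, such as the smooth muscle actin ACTA2 (27.6 to 10.2, -1.39) and the AP-1 subunit FOSL2 (21.5 to 11.8, -0.82). Its median was 0.487 above that of all genes (camera adjusted p = 0.00298; adjusted p = 0.923 with an estimated correlation). On unnormalised values 17 rose and 3 fell (camera adjusted p = 8.92e-05, and adjusted p = 0.164 with an estimated correlation).

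Other lists held falling members at 24 h without a call for the list on the spike-in scale. Mitosis genes fell in 12 of 24 (list adjusted p = 0.353), among them the ubiquitin-conjugating enzyme UBE2C (521 to 155 FPKM, -1.77) and the kinases AURKB (159 to 58.3, -1.45) and CDK1 (151 to 58.7, -1.37). DNA replication genes fell in 11 of 25 (adjusted p = 0.106), among them the licensing factor CDT1 (48.3 to 20.0, -1.25). Targets of p53 fell in 9 of 21 (adjusted p = 0.223), with the nuclease AEN at 53.9 to 15.8 (-1.71). Heat shock genes fell in 7 of 15 (adjusted p = 0.134), such as the co-chaperone FKBP4 (173 to 63.1, -1.46). Glycolysis genes fell in 7 of 20 (adjusted p = 0.121), such as hexokinase HK2 (24.1 to 6.88, -1.69), and nuclear-encoded oxidative phosphorylation genes in 8 of 25 (adjusted p = 0.104), such as COX5A (298 to 155, -0.96). RNA polymerase II and elongation genes fell in 8 of 25 (adjusted p = 0.369), among them the pausing factor subunit NELFA (-0.94). On unnormalised values mitosis genes split 7 higher and 13 lower, p53 targets 5 and 9, and RNA polymerase II genes 5 and 14, without a camera call. Fry called each of them lower there (adjusted p = 8.38e-07, 1.53e-06 and 1.92e-06). DNA replication (4 and 16, adjusted p = 0.0162) and heat shock genes (8 lower, adjusted p = 0.0498) were called lower there, each lost at adjusted p = 0.44 with an estimated correlation. Glycolysis (2 and 15, adjusted p = 0.0132) and oxidative phosphorylation genes (1 and 17, adjusted p = 0.00836) were called lower too, each lost at adjusted p = 0.472 with an estimated correlation.

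Several lists moved both ways at 24 h without a call on the spike-in scale. Of 17 integrated stress response genes 2 rose, such as the mTORC1 inhibitor DDIT4 (17.7 to 46.4 FPKM, +1.32), and 9 fell, such as the amino acid transporter SLC7A5 (-1.40; list adjusted p = 0.585). Among 17 endoplasmic reticulum chaperones and partners SEL1L rose (+0.89) and 5 fell, such as the stress factor XBP1 (-1.18; list adjusted p = 0.774). Cholesterol synthesis had 2 higher, such as the sterol carrier STARD4 (+0.55), and 2 lower, such as DHCR7 (-0.85), of 19 (list adjusted p = 0.259). The MYC and MAX network had 4 higher and 12 lower of 20 (list adjusted p = 0.353), with the inhibitor ID3 at 368 to 158 (-1.22) and MAX at 44.3 to 22.6. Lysosome and autophagy genes had 2 higher, such as LAMP2 (+0.69), and 2 lower, such as the channel MCOLN1 (-1.01), of 25 (list adjusted p = 0.102). On unnormalised values lysosome and autophagy genes split 14 higher and 4 lower and were called higher (adjusted p = 0.00323; adjusted p = 0.44 with an estimated correlation). BET inhibitor response genes had 3 higher, such as ZCCHC24 (+0.81), and 4 lower, such as CCND1 (-1.85), of 16 (list adjusted p = 0.168). Neuronal differentiation genes had 2 higher, such as the microtubule protein MAP1B (31.3 to 54.3, +0.76), and 2 lower, such as the secreted peptide precursor VGF (11.5 to 3.66, -1.42), of 9 (list adjusted p = 0.362). Adrenergic identity genes fell in 4 of 8 (list adjusted p = 0.821), such as GATA2 (15.7 to 6.37, -1.19), but split 4 and 4 on unnormalised values. There the splits without a camera call were 4 and 8 for the stress response, 5 and 9 for chaperones, 8 and 5 for cholesterol synthesis, 6 and 12 for the MYC and MAX network, 7 and 3 for BET inhibitor response and 4 and 2 for neuronal differentiation. Fry called each of these there, at adjusted p from 5.42e-08 (MYC and MAX network, lower) to 0.027 (neuronal differentiation, higher). Of these lists, the MYC and MAX network and BET inhibitor response hold MYCN itself among their lower genes. Fry called both lower on unnormalised values, BET inhibitor response at adjusted p = 0.000322 with 7 higher and 3 lower. It was not run without MYCN, so those calls rest in part on the targeted gene. With camera and without MYCN, a test chosen after seeing the data, the first list had 4 higher and 11 lower of 19 (adjusted p = 0.761). The second, with 3 and 3 of 15, was called higher (adjusted p = 0.0292; adjusted p = 0.925 with an estimated correlation), but not on unnormalised values (adjusted p = 0.145). None of 13 replication histones (list adjusted p = 0.299) and none of 3 epithelial genes (list adjusted p = 0.223) passed in limma, with 0 in each list at an unadjusted p under 0.05. KRT8, one of the 3 epithelial genes that pass on unnormalised values, went from 548 to 637 FPKM.

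Few genes passed at 2 h and 4 h, and lower genes were most numerous at 24 h. At 2 h 6 genes were lower and none higher in limma (194 at an unadjusted p under 0.05), and at 4 h 9 were lower and 1 higher. Without the 2 h library numbered 2, 64 were higher and 6 lower at 2 h. At 4 h 38 were higher and 20 lower with a pseudocount of 0.1, and 18 and 33 without the 4 h library numbered 2. Libraries of other times turned that balance through the pooled spread, to 19 and 16 without 6 h number 1, 162 and 33 without 6 h number 2, and 148 and 49 without 16 h number 0. Besides MYCN, EDN1, which encodes endothelin 1, fell early, from 11.6 FPKM to 5.23 at 2 h (-1.03, adjusted p = 0.00802) and 4.31 at 4 h (-1.26, adjusted p = 0.000479). The call at 2 h was lost without the 0 h library numbered 1 or 2 (adjusted p = 0.121 and 0.149) or the 2 h library numbered 1 (adjusted p = 0.0577). The gene higher at 4 h was BOD1L1, a replication fork protein (2.03 to 5.45, +1.08, adjusted p = 0.0493). BOD1L1 passed with only 1 of the 5 libraries compared left out, 4 h number 2, and otherwise lost its call (adjusted p = 0.166 to 0.886), as it did without the filter (adjusted p = 0.0791). Lower at 4 h were also the MAX partner MNT (-1.14, adjusted p = 0.0355), the E-box factor TFAP4 (-1.03, adjusted p = 0.0355), CD3EAP (-1.14, adjusted p = 0.00556), and the BMP antagonist NOG (-0.95, adjusted p = 0.0118). These 4 genes were chosen after their values were seen. Without the 0 h library numbered 2 none of them passed (adjusted p = 0.192 for CD3EAP, 0.153 for NOG, 0.886 for MNT and 1 for TFAP4). Of the 5 libraries compared, MNT and TFAP4 passed only with 4 h number 2 left out. NOG did not pass without 0 h number 1 (adjusted p = 0.132) or 4 h number 1 (adjusted p = 0.0725) either. At 6 h 376 genes were higher and 895 lower, with the median gene at -0.14 (-0.221 without the 0 h library numbered 1 and -0.064 without number 2). FAM111B (1.98 to 7.66, +1.51) and DDIT4 (17.7 to 41.9, +1.21) rose and FJX1 fell (34.7 to 9.60, -1.75, adjusted p = 0.000342). At 8 h the counts were 465 and 454. Higher were EPGN (20.4 FPKM, +1.65) and the histone gene HIST1H2AC (4.41 to 14.7, +1.53, adjusted p = 0.0136). At 16 h they were 609 and 361, with TM7SF2, a sterol reductase, higher (0.994 to 5.03, +1.59) and ECE2 lower (11.3, -1.85). The counts and calls from 6 h to 16 h moved too when single libraries were left out. DDIT4 at 6 h lost its call without the 0 h library numbered 1 (adjusted p = 0.0665), and HIST1H2AC at 8 h without number 1 or 2 (adjusted p = 0.0998 and 0.136). Without the 0 h library numbered 2, 8 genes were higher and 36 lower at 6 h, 11 and 25 at 8 h, and 55 and 24 at 16 h. At 8 h the counts were 80 and 137 without the 0 h library numbered 1, 86 and 148 without the 8 h library numbered 0, 158 and 338 without number 1, and 321 and 163 without number 2. At 16 h they were 291 and 580 without the 16 h library numbered 1, and 1289 and 195 without number 0. RRP9 fell at 6, 8, 16 and 24 h (-0.90, -1.19, -1.40, -1.90) without passing at 2 h or 4 h. Unnormalised values gave 28 higher and 41 lower at 2 h, 1880 and 2142 at 4 h, 3186 and 3538 at 6 h, 2966 and 3471 at 8 h, and 2820 and 3260 at 16 h.

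Immediate early genes were below the other genes from 2 h to 8 h and ribosome biogenesis from 6 h on. The immediate early list median stood at -0.163 against all genes at 2 h (adjusted p = 6.86e-09; adjusted p = 0.823 with an estimated correlation) and -0.428 at 4 h (adjusted p = 7.34e-11; adjusted p = 0.995 with an estimated correlation). At 2 h, where no member passed alone, heat shock genes lay below the other genes (-0.160, adjusted p = 4.85e-08; adjusted p = 0.823 with an estimated correlation, 0.00486 on unnormalised values and 0.0667 after centring). Mitosis genes lay above them (0.190, adjusted p = 1.97e-07; adjusted p = 0.902 with an estimated correlation, 0.0135 on unnormalised values and 0.0667 after centring). Endoplasmic reticulum chaperones lay below them (-0.112, adjusted p = 0.00737; adjusted p = 0.991 with an estimated correlation, 0.0482 on unnormalised values and 0.0675 after centring). Replication histones lay above in 2 of the 3 libraries (1.694, adjusted p = 1.03e-33; adjusted p = 0.0421 with an estimated correlation, 0.335 on unnormalised values and 0.186 after centring). Immediate early genes fell in 14 of 19 at 6 h (list median -0.640 against all genes, adjusted p = 3.04e-10; adjusted p = 0.964 with an estimated correlation). They fell in 9 of 19 at 8 h (adjusted p = 2.77e-08; adjusted p = 0.993 with an estimated correlation). At 16 h the list had no call (1 higher, 2 lower, -0.053, adjusted p = 0.471). Ribosome biogenesis genes fell in 9 of 30 at 6 h, 7 at 8 h and 5 at 16 h (19 when adjusted over the list alone). The list median was -0.279 at 6 h (adjusted p = 0.0141; adjusted p = 0.964 with an estimated correlation). It was -0.437 at 8 h and -0.543 at 16 h against all genes (adjusted p = 5.68e-06 and 8.38e-09; adjusted p = 0.993 and 0.975 with an estimated correlation). With an estimated correlation that list held on unnormalised values at 8 h (adjusted p = 0.0326) and 16 h (adjusted p = 0.0121), and after centring at neither (adjusted p = 0.456 and 0.151). Interferon-response genes (4 of 16 higher, 0.333) and mesenchymal genes (2 of 29 higher, 0.323) lay above the other genes at 16 h (adjusted p = 7.09e-04 each; adjusted p = 0.975 with an estimated correlation). On unnormalised values 11 and 19 rose. With an estimated correlation the first list held there (adjusted p = 0.0178) but not after centring (0.109), and the second did not hold on unnormalised values (adjusted p = 0.0716). The tight-junction gene CLDN4, of the epithelial list, rose at 16 h (6.91 to 19.1 ± 4.43 FPKM, +1.33, adjusted p = 0.00101).

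**Figure D2:**
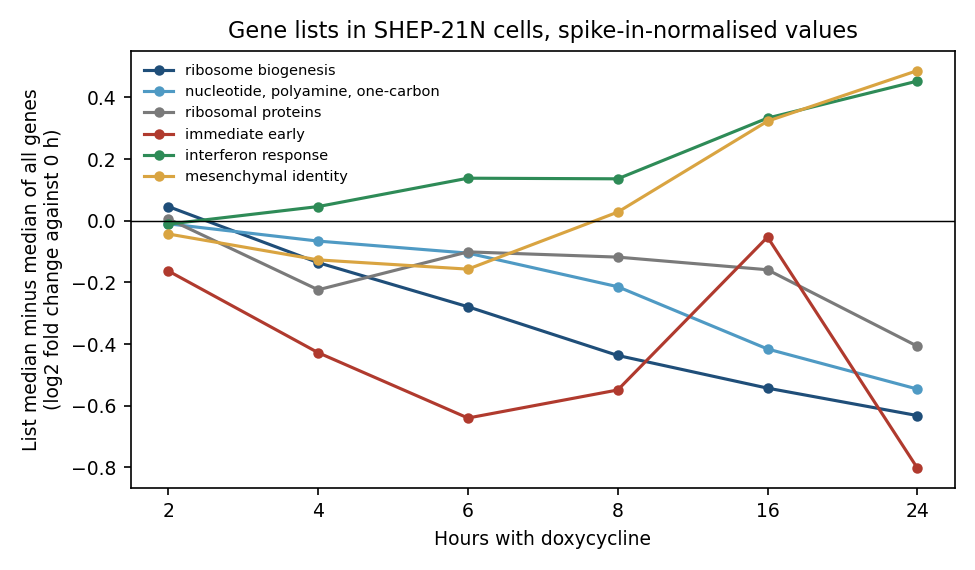
Median log2 fold change against 0 h of 6 gene lists minus the median of all tested genes, against hours with doxycycline (2 to 24 h) in SHEP-21N cells, from spike-in-normalised FPKM. At 24 h ribosome biogenesis stands at -0.632, immediate early genes at -0.802 and interferon-response genes at 0.453.

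TWIST1 RNA fell in BE(2)-C cells with the hairpin, which passed from 24 h on. The 3 libraries without doxycycline held 91.8, 70.3 and 82.0 FPKM and those at 48 h 7.65, 11.2 and 4.60. The mean went from 81.4 ± 10.8 FPKM to 42.1 ± 8.98 at 3 h (n = 3, adjusted p = 0.411), 51.7 ± 16.2 at 6 h (adjusted p = 0.943) and 35.5 at 12 h (adjusted p = 0.59). It reached 21.1 ± 2.94 at 24 h (-1.90, adjusted p = 0.00253) and 7.81 ± 3.30 at 48 h (-3.29, SE 0.339, adjusted p = 4.12e-08). On unnormalised values it went from 64.9 ± 8.69 to 18.1 ± 0.684 FPKM (-1.78, adjusted p = 9.3e-09) and passed from 6 h on (-0.93, adjusted p = 0.000245). The unnormalised libraries held 20.6, 20.4 and 19.2 FPKM at 24 h and 18.9, 17.7 and 17.7 at 48 h. Most of the further fall from 24 h to 48 h on the spike-in scale was therefore shared with the median gene. MYCN, at 1153 ± 287 FPKM without doxycycline, fell at 48 h to 322 ± 134 (-1.89); on unnormalised values it went from 900 ± 10.8 to 784 ± 12.3 (-0.20, adjusted p = 0.00275).

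Nearly all genes were lower at 48 h on the spike-in scale: 10667 of 11433 tested were lower and 15 higher. The 15 were all short RNAs, with names starting MIR, SNORA or SNORD. The median gene fell by 1.36 on the log2 scale. Library medians were 2.61 ± 0.529 against 4.03 ± 0.417 (n = 3 each; exact permutation p = 0.1, two-sided, the smallest possible). On unnormalised values, where the median moved by 0.02 (exact permutation p = 1), 2067 genes were higher and 2434 lower (45.9% of changed genes higher, against 0.1%), and after centring 3496 and 2500 (58.3%). Centring was done after 1 FPKM was added, so it lifted weakly expressed genes, which could not fall as far as the median gene. The count of genes higher after centring includes that effect. The unnormalised spike-in totals differed, 28224 ± 7881 FPKM without doxycycline and 96120 ± 41554 at 48 h. Changes relative to the median gene are therefore given from the unnormalised values for genes and lists at 48 h, with the spike-in values where stated. The no-doxycycline library numbered 1 stood apart there, with a total of 1028218 FPKM against 792122 and 736423. No unnormalised gene or list call was checked without it. Unnormalised changes also went with 3′ UTR GC content and log length across genes (Pearson's r -0.275 and 0.424 at 3 h, -0.309 and 0.111 at 48 h).

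**Figure D3:**
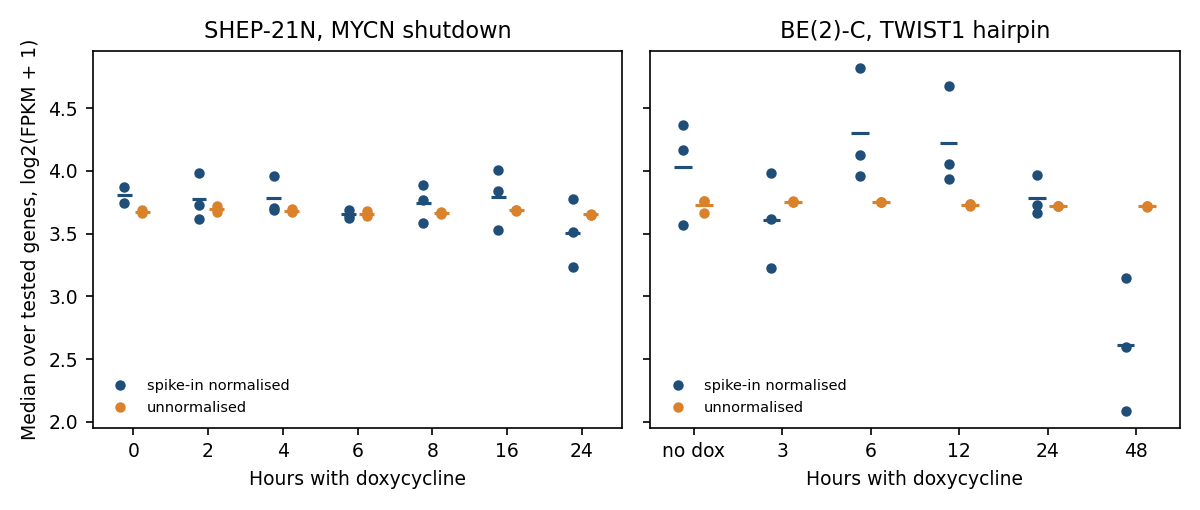
Median of log2(FPKM + 1) over the tested genes in each library of SHEP-21N and BE(2)-C hairpin cells, against hours with doxycycline, on spike-in-normalised and unnormalised scales. On the spike-in scale the median moved by -1.364 at 48 h of hairpin expression.

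PIK3R2, HNRNPUL1, STRN4 and OAF fell further than TWIST1 at 48 h on both scales. PIK3R2, the PI 3-kinase subunit p85-beta, fell from 92.6 ± 22.0 to 3.31 ± 1.36 FPKM (-4.46, adjusted p = 2.49e-10, unnormalised 7.53 FPKM at 48 h, -3.11). The RNA-binding protein HNRNPUL1 fell from 151 to 6.27 (-4.39, unnormalised -2.90), the striatin STRN4 from 62.4 to 2.95 (-4.01, unnormalised -2.67) and the secreted protein OAF from 39.3 to 1.87 (-3.83, unnormalised -2.66). Spinophilin PPP1R9B (unnormalised -2.44), the COPII and nuclear pore protein SEC13 (76.1 to 16.3, -2.15), the mannosyl transfer subunit DPM3 (-2.11), the matrix protein EMILIN1 (-1.96), neurogranin NRGN (-2.15) and guanylate kinase GUK1 (-1.76) fell on both scales. Applied to unnormalised values, an addition chosen after seeing the data, the same rule also names the falls PRKCZ, an atypical protein kinase C (9.29 to 1.01, -2.35), and PPP1R16B (34.6 to 7.64, -2.02). It names as rises HIGD1C (6.29 to 26.7, +1.95), the growth factor HGF (5.0 ± 1.44 to 18.3 ± 1.04, +1.72, adjusted p = 8.98e-08) and the calcium channel subunit CACNA2D1 (13.4 ± 9.11 to 35.1 ± 1.24, +1.66). Other rises are the potassium channel KCNJ2 (1.52 to 5.70, +1.44), TMEM245 (+1.37), the vesicular monoamine transporter SLC18A2 (4.05 to 11.8, +1.36), the vesicle protein SYT4 (8.57 to 23.0, +1.34), FLRT3 (+1.30) and ARHGAP36 (+1.26). BLOC1S5-TXNDC5 (+1.58) is a readthrough name whose reads 2 other genes share. None of these 10 rises passed on the spike-in scale in limma (HGF 0.27, SYT4 -0.15), where 10726 genes had an unadjusted p under 0.05. Single libraries were left out on the spike-in scale only, so the unnormalised rises were not checked in that way. Without the no-doxycycline library numbered 1, CACNA2D1 stood there at -0.886 with the median gene at -1.578. With all libraries it stood at 0.086 with the median gene at -1.364. Genes whose 3′ UTR holds ACGAGGA, a 7-base sequence also found in TWIST1 mRNA, had a mean of -0.259 at 48 h on unnormalised values (-0.209 once 3′ UTR length and base composition were removed).

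Most tested cholesterol synthesis and mitosis genes fell at 48 h on unnormalised values. There 14 of 19 cholesterol genes fell and 1 rose (list median -0.448 against all genes, camera adjusted p = 0.000161; adjusted p = 0.0362 with an estimated correlation). Among them were the synthase HMGCS1 (56.9 to 26.7 FPKM, -1.05, adjusted p = 8.2e-07), the squalene epoxidase SQLE (105 to 65.2, -0.68) and the kinase MVK (-0.66). Mitosis genes fell in 13 of 24 with 1 higher (-0.297, adjusted p = 0.000161; adjusted p = 0.0156 with an estimated correlation). After centring camera called both lists lower (adjusted p = 4.66e-07 and 1.96e-07), calls that were lost with an estimated correlation (adjusted p = 0.221 and 0.263). Examples are UBE2C (458 to 295, -0.61) and the transcription factor FOXM1 (115 to 76.1, -0.59). DNA replication genes fell in 13 of 25 with 2 higher (adjusted p = 0.0121; adjusted p = 0.255 with an estimated correlation), such as the helicase subunit MCM3 (-0.61) and E2F1 (66.2 to 44.9, -0.54). MYC and MAX network genes, a list that holds the targeted TWIST1, fell in 7 of 16 without TWIST1, with no call for the list (adjusted p = 0.109; with TWIST1, 8 of 17, adjusted p = 0.0409, and adjusted p = 0.255 with an estimated correlation), such as the helix-loop-helix genes TCF3 (50.1 to 30.1, -0.72) and ID1 (86.6 to 53.4, -0.66). Mesenchymal genes fell in 8 of 13 with 2 higher (adjusted p = 0.0474; adjusted p = 0.272 with an estimated correlation), such as LGALS1 (722 to 406, -0.77). On the spike-in scale, where nearly every member fell, cholesterol (-0.635 against all genes, adjusted p = 0.00269) and mitosis genes (-0.551, adjusted p = 0.00269) were called lower. DNA replication (-0.413, adjusted p = 0.012) and oxidative phosphorylation (-0.290, adjusted p = 0.0189) were called lower too. Each of these 4 calls was lost at adjusted p = 0.956 with an estimated correlation, with which no list passed on that scale. Without the no-doxycycline library numbered 1 the calls of DNA replication (adjusted p = 0.0705) and oxidative phosphorylation (adjusted p = 0.753) were lost too. The MYC and MAX network was called only with TWIST1 in it (adjusted p = 0.0315; adjusted p = 0.956 with an estimated correlation; 0.108 without TWIST1). After centring it was called lower without TWIST1 (adjusted p = 0.0237; adjusted p = 0.304 with an estimated correlation). The tests without TWIST1 were chosen after seeing the data. Ribosomal proteins went the other way between scales. All 30 fell on the spike-in scale (list adjusted p = 0.253), while 8 rose on unnormalised values (list adjusted p = 0.00993; adjusted p = 0.7 with an estimated correlation) and the list stood lower after centring (adjusted p = 0.411).

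The remaining lists had no camera call at 48 h on either scale, apart from oxidative phosphorylation on the spike-in scale. Splits give the members passing on unnormalised values. Except for SLC18A2, genes named here were picked by adjusted p on the spike-in scale, where nearly all genes fell. Fry called every list lower on that scale (adjusted p of 0.0044 or less). On unnormalised values fry called, among others, adrenergic (adjusted p = 8.05e-06) and interferon-response genes (1.76e-05) higher. It called neuronal (1.74e-06) and immediate early genes (7.65e-05) lower. Neuronal differentiation genes split 7 higher and 10 lower of 24 (list adjusted p = 0.259), with the microtubule genes STMN2 (473 to 190 FPKM, -1.31) and TUBB3 (381 to 182, -1.04) falling. Adrenergic identity genes split 9 and 4 of 24 (list adjusted p = 0.109). Of these the transporter SLC18A2 rose, as given above, the transcription factor HAND2 fell (225 to 151, -0.56) and the granin CHGA did not pass (1906 to 1674, adjusted p = 0.231). Immediate early genes split 2 and 9 of 17 (list adjusted p = 0.109), with EGR1 at 8.34 to 3.32 (-1.12) and IER2 at 44.1 to 23.6 (-0.86). Oxidative phosphorylation genes split 1 and 2 of 25 (list adjusted p = 0.895), with the succinate dehydrogenase subunit SDHC falling (53.1 to 18.3, -1.49). RNA polymerase II genes split 4 and 6 of 25 (list adjusted p = 0.625), with the elongation factor SUPT5H falling (-0.95), and glycolysis genes 4 and 4 of 19 (list adjusted p = 0.895), with the kinase PFKP falling (14.6 to 6.05). Ribosome biogenesis genes split 4 and 6 of 30 (list adjusted p = 0.895) and nucleotide genes 9 and 1 of 26 (list adjusted p = 0.263). The integrated stress response split 6 and 1 of 18 (list adjusted p = 0.11), and endoplasmic reticulum chaperones 7 and 3 of 17 (list adjusted p = 0.179), with CALR falling (505 to 315). Heat shock genes split 2 and 3 of 15 (list adjusted p = 0.922), p53 targets 5 and 3 of 18 (list adjusted p = 0.554), and interferon-response genes 3 and 1 of 11 (list adjusted p = 0.179). Lysosome and autophagy genes split 7 and 4 of 25 (list adjusted p = 0.353). BET inhibitor response genes split 3 and 3 of 14 (list adjusted p = 0.895), with ZCCHC24 falling (4.07 to 1.12). Of 4 replication histones 1 rose (list adjusted p = 0.434). After centring camera called ribosome biogenesis (adjusted p = 0.00855), oxidative phosphorylation (0.00212), neuronal differentiation (0.0237), glycolysis and heat shock genes (0.0402 each) lower. It called interferon-response genes higher there (adjusted p = 0.0321, 7 of 11 higher). Since centring lifts weakly expressed genes at this time, that call is no separate evidence of a rise. These calls after centring were lost with an estimated correlation (adjusted p = 0.437 to 0.654).

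Few genes passed before 24 h of hairpin expression on the spike-in scale. At 3 h MIR636 and MIR658 were higher and SNORD76 and SNORD9 lower. At 6 h MIR658 and SNORA71A were higher and OAF and SNORD9 lower, and at 12 h MIR2861 and MIR658 were higher and OAF, SNORD9 and STRN4 lower. Apart from OAF and STRN4 these are short RNAs, named after their values were seen, which selection of polyadenylated RNA is not made to capture. OAF fell from 39.3 FPKM to 11.6 at 6 h (-1.71, adjusted p = 0.0114) and 8.53 at 12 h (-2.09, adjusted p = 0.000491), and STRN4 to 19.0 at 12 h (-1.66, adjusted p = 0.0267). OAF at 6 h lost its call without the 6 h library numbered 0 or 2 (adjusted p = 0.134 and 0.206). STRN4 at 12 h lost it without any of 4 of the 6 libraries compared (adjusted p = 0.113 to 0.283). At 24 h 67 genes were lower, led by PIK3R2 (10.3 FPKM, -3.02, adjusted p = 1.59e-06), HNRNPUL1 (18.4, -2.91) and STRN4 (7.69, -2.85), and 2 higher, SNORA5C and SNORA71A. Unnormalised values gave 2 lower at 3 h, OAF (-0.81, adjusted p = 0.0124) and the nucleolar protein NOL10 (-0.40, adjusted p = 0.0124), with none higher in limma (557 at an unadjusted p under 0.05). They gave 1 higher and 54 lower at 6 h, 86 and 381 at 12 h, and 1092 and 1551 at 24 h. The median gene moved by -0.43, 0.22, 0.19 and -0.22 at 3, 6, 12 and 24 h on the spike-in scale (n = 3; exact permutation p = 0.3, 0.6, 0.6 and 0.4). With single libraries left out the shift ran from -0.627 to -0.24 at 3 h, -0.018 to 0.374 at 6 h, -0.021 to 0.331 at 12 h and -0.41 to -0.075 at 24 h, so that it turned sign at 6 h and 12 h. Of the 12 h libraries, the one numbered 2 held MYC at 9.69 FPKM against at most 0.253 in the other 17.

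Signalling and sterol genes were among the groups below the others at 24 h of hairpin expression. Immediate early genes were called lower at 3, 6, 12 and 24 h on the spike-in scale (adjusted p = 0.0178, 6.66e-08, 1.62e-08 and 6.7e-05; lost in each with an estimated correlation, adjusted p = 0.938 to 0.985). EGR1 went on unnormalised values from 8.34 FPKM to 3.53 at 6 h (adjusted p = 0.023) and 2.48 at 24 h. At 24 h on unnormalised values immediate early genes fell in 9 of 17 with 1 higher (adjusted p = 0.00419; adjusted p = 0.179 with an estimated correlation). Cholesterol genes fell in 11 of 19 with 1 higher (adjusted p = 0.000977; adjusted p = 0.107 with an estimated correlation). Adrenergic identity genes were called higher there (9 higher, 2 lower of 24, adjusted p = 0.0285; adjusted p = 0.184 with an estimated correlation), a list with no call on the spike-in scale. DNA replication genes (10 of 25 lower), mitosis genes (6 of 24 lower, 1 higher) and mesenchymal genes (6 of 13 lower, 1 higher) were called lower there at adjusted p = 0.0253, 0.0253 and 0.0316. Those calls were lost at adjusted p = 0.184, 0.146 and 0.184 with an estimated correlation. HGF had already risen at 24 h (+0.90 on unnormalised values).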

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

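The tests of the 48 h fall in this part were chosen only after it was seen. The total of spike-in RNA in the unnormalised values of the hairpin experiment, a measure the comparisons of genes do not use, was 3.41 times higher at 48 h (96120 ± 41554 FPKM) than without doxycycline (28224 ± 7881; n = 3 each; exact permutation p = 0.1, two-sided, the smallest possible), which is why it is given here as a signal outside the main measurement. It is the counterpart of the fall of nearly all genes on the spike-in scale, where 99.3% of tested genes lie below 0.

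A rescaling that acts mainly on weakly expressed genes is argued against as the whole source of that fall: genes at 100 FPKM or more moved by -1.675 between the scales (969 genes), close to the -1.629 of genes at 10 to 100 and beyond the -1.512 of genes at 1 to 10. A lower RNA content per cell at 48 h, and more spike-in RNA or fewer cells per tube than intended, cannot be told apart here, since each needs a higher spike-in total, as the ratio of 3.41 shows, and no cell number per library is given. Loss of TWIST1, the named biological difference, stays open and untested for this pattern.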

How the results depend on the processing

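The settings without the 12 h library numbered 2 and without the targeted gene in the lists were chosen after seeing the data; the others were planned. MYCN kept its direction and its call at all 6 times under unnormalised values, centring, a pseudocount of 0.1, no filter and each library left out. TWIST1 kept its direction in those settings and its call at 24 h and 48 h. The counts at the latest times stayed within 1.5 times without the intensity trend, and for SHEP-21N with 2 h as the reference. No paired analysis was possible because the columns are matched to groups only and no label ties a number in one group to the same number in another, and the planned JQ1 comparisons were not run.

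On unnormalised values SHEP-21N gave 69, 4022, 6724, 6437, 6080 and 7754 changed genes at 2, 4, 6, 8, 16 and 24 h and 9721 over any time, against 6, 10, 1271, 919, 970, 4579 and 3683 on the spike-in scale; after centring these were 39, 3218, 6081, 5601, 5594, 7338 and 9149. The median shift at 6 h went from -0.142 to -0.015 (0.013 after centring, -0.011 without the filter) and at 24 h from -0.308 to -0.038 (-0.007 after centring). List calls at 24 h went from 6 to 11 on unnormalised values, 10 after centring and 11 without the filter, where the adrenergic list turned direction with no call (adjusted p = 0.995). A pseudocount of 0.1 gave 58 genes at 4 h. The cause was not tested, nor which scale is nearer to RNA per cell.

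For the hairpin, unnormalised values gave 2, 55, 467, 2643 and 4501 changed genes at 3, 6, 12, 24 and 48 h and 3749 over any time, against 4, 4, 5, 69, 10682 and 10970; centring gave 45, 290, 2037 and 5996 from 6 h on and 5028 over any time, a pseudocount of 0.1 gave 10, 7 and 15 at 3, 6 and 12 h, and no filter gave 0 at 3 h and 1 at 6 h in limma, with 687 and 333 genes at an unadjusted p under 0.05. The median shift at 3 h was -0.003 on unnormalised values and -0.004 after centring, and at 48 h it turned to 0.021 and 0.059. TWIST1 passed at 6 h (-0.925 on unnormalised values, -0.947 after centring) and 12 h (-1.383 and -1.391). List calls at 48 h went from 5 to 10 after centring, 3 with the pseudocount and 14 without the filter; the cause was not tested.

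At 48 h the direction of these lists reversed on unnormalised values: nucleotide (adjusted p = 0.263), glycolysis (0.895), ribosomal proteins (0.00993), endoplasmic reticulum chaperones (0.179), heat shock (0.922), adrenergic (0.109), lysosome (0.353) and BET inhibitor response (0.895). With a pseudocount of 0.1 the adrenergic (0.851) and BET (0.969) lists reversed, as they did without the 12 h library numbered 2 (0.961 and 0.968), and without the filter the stress response (0.734) and mesenchymal (0.896) lists did. Over single libraries left out, adjusted p ran from 0.0242 to 0.273 for ribosomal proteins, 0.376 to 0.933 for chaperones, 0.378 to 0.977 for the adrenergic list, 0.211 to 0.904 for lysosome and 0.825 to 0.999 for BET. Of the lists called, it ran from 0.00266 to 0.0705 for DNA replication, 0.00131 to 0.753 for oxidative phosphorylation and 0.0194 to 0.0529 for the MYC and MAX network. Named genes that reversed at 48 h on unnormalised values were RPS15 (0.029), RPL35 (0.063) and RPS28 (0.03), and after centring BBC3 (0.159), OAS1 (0.009) and HIST1H2AJ (0.429). Those that reversed in both were IFIT5 (0.187 and 0.144), OAS3 (0.197 and 0.092), IFI6 (0.283 and 0.279), HIST1H2BO (0.151 and 0.365), HIST1H3H (0.377 and 0.524), HIST1H3G (0.297 and 0.689), S100B (0.359 and 0.536), KRT19 (0.223 and 0.261) and HBB (0.097 and 1.418; -0.031 to 0.039 with single libraries left out). HBB stood near the floor, at 0.0304 FPKM without doxycycline and 0.101 at 48 h on unnormalised values. It was tested only because of its values at 3 h (12.9 ± 22.2). Of the rises named on unnormalised values, these were below 0 on the spike-in scale and reversed in both: TMEM245 (1.374 and 1.263; -0.641 to 0.151 with single libraries left out), SLC18A2 (1.361 and 1.413; -0.335 to 0.233), SYT4 (1.342 and 1.268; -0.523 to 0.187) and FLRT3 (1.298 and 1.277; -0.479 to 0.161). With single libraries left out HGF (-0.129 to 0.586), CACNA2D1 (-0.886 to 0.643), BLOC1S5-TXNDC5 (-0.01 to 0.949), KCNJ2 (-0.066 to 0.481) and ARHGAP36 (-0.031 to 0.331) reversed. CACNA2D1 alone of these passed as lower on the spike-in scale, without the no-doxycycline library numbered 1 (-0.886, adjusted p = 0.0296). Centring after the addition of 1 FPKM lifts weakly expressed genes when the median falls. HBB shows it, at 0.142 and 0.138 FPKM on the spike-in scale without doxycycline and at 48 h, yet at 1.418 after centring. Any other cause of these reversals was not tested.

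Leaving out each library of the 2 compared groups in turn gave 3 to 70 changed genes at 2 h in SHEP-21N cells, 7 to 51 at 4 h, 44 to 1104 at 6 h, 36 to 496 at 8 h, 79 to 1484 at 16 h, 876 to 5990 at 24 h, and each of the 20 gave 2269 to 5663 over any time. With 1 library left at 0 h, that library is assumed to vary like the other groups. Without the 0 h library numbered 2 the counts were 44, 36, 79 and 876 at 6, 8, 16 and 24 h and 2323 over any time; without that numbered 1 they were 317, 217 and 262 at 6, 8 and 16 h. Libraries of the compared time that moved a count beyond 1.5 times were, at 2 h, number 1 (3) and 2 (70); at 4 h, 2 (51); at 6 h, 0 (638) and 2 (155); at 8 h, 0 (234), 1 (496) and 2 (484); at 16 h, 0 (1484) and 2 (329); at 24 h, 2 (2779), with 0 (5663) and 1 (2269) for any time. For the hairpin the ranges were 2 to 18 at 3 h, 2 to 16 at 6 h, 3 to 20 at 12 h and 29 to 142 at 24 h. Without the no-doxycycline libraries numbered 0, 1 and 2 these were 10, 18 and 13 at 3 h and 8, 16 and 9 at 6 h; without numbers 0 and 1 they were 12 and 20 at 12 h and 35 and 142 at 24 h. Of the compared times, 3 h number 0 (2), 6 h number 2 (2), 12 h number 2 (3) and 24 h numbers 0, 1 and 2 (31, 32 and 29) did so. Libraries of other groups enter through the pooled spread and moved these counts too: in SHEP-21N cells 6 h numbers 1 (35) and 2 (195) and 16 h number 0 (197) at 4 h, and 16 h number 0 (1414) at 8 h; for the hairpin 6 h number 0 (7), 12 h number 1 (2) and 48 h number 1 (2) at 3 h, and 24 h number 2 (8) at 12 h. List calls at 48 h ran from 4 to 10, the latter without 48 h number 1.

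Of 124 comparisons of named genes in SHEP-21N cells only KRT18 at 24 h reversed (0.256 on unnormalised values, 0.287 after centring, -0.217 to 0.189 with single libraries left out; the cause was not tested). Another 2 gained a call on unnormalised values and 2 after centring, 4 lost theirs without the filter, and over single libraries left out 536 kept the call or its absence and 82 lost the call. For the hairpin, of 118 comparisons 75 kept the call or its absence on unnormalised values, 6 gained it and 21 lost it; 85, 6 and 11 did so after centring, 116, 0 and 2 without the filter, and 678, 1 and 9 over single libraries left out. Without the targeted gene list calls went from 6 to 7 at 24 h in SHEP-21N cells and from 5 to 4 at 48 h of the hairpin.

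Without read numbers, what depth limits could not be separated from the spread between replicates. In simulations for the hairpin at 48 h, with few genes changed, 22.4% of changes of 1 on the log2 scale were found. In the real comparison 10682 genes passed, which makes the adjusted p easier to reach, so 22.4% is not the share found there. A gene that did not pass at 48 h may still have changed. On unnormalised values 4501 genes passed there.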

Other observations

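The tests of sites in 3′ UTRs, except that in SHEP-21N cells, the comparison of 16 h with 8 h and 24 h, and the tests of the 12 h library, except the medulloblastoma list, were chosen only after the results were seen. EDN1 and EGR1, lower at 8 h of MYCN shutdown than at 0 h, were higher at 16 h than at 8 h or 24 h. EDN1 stood at 11.6 FPKM at 0 h, 3.92 at 8 h, 11.9 ± 2.09 at 16 h and 4.00 at 24 h (n = 2 at 0 h, 3 later; 8 h minus 16 h -1.38, SE 0.14, adjusted p = 2.77e-05; 24 h minus 16 h -1.36, adjusted p = 2.02e-05). EGR1 went 1.75, 3.96 and 1.12 FPKM over 8, 16 and 24 h (-0.85, adjusted p = 0.00406, and -1.23, adjusted p = 0.000119, against 16 h), and FOSL1, at 129 FPKM at 0 h, went 57.7, 81.6 and 27.8 (-0.47, adjusted p = 0.387, and -1.51, adjusted p = 0.00035). Of 19 immediate early genes 9 were lower at 8 h than at 16 h (camera adjusted p = 1.69e-11; adjusted p = 0.859 with an estimated correlation) and 16 were lower at 24 h (1.29e-20; adjusted p = 0.422 with an estimated correlation, 0.037 on unnormalised values and 0.0495 after centring). On unnormalised values EDN1 differed by -1.35 and -1.11, EGR1 by -0.81 and -1.01 and FOSL1 by -0.48 and -1.26.

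Replication histone RNA, which mostly lacks a poly(A) tail, stood out in 2 of the 3 libraries at 2 h in SHEP-21N cells. The median of 13 such genes was 8.42, 14.1 and 0.546 FPKM in the libraries numbered 0, 1 and 2 on unnormalised values, against 0.343 to 2.71 in the other 17. HIST1H4C stood at 16.8, 20.0 and 1.14 and HIST1H1B at 7.94, 13.2 and 0.237.

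Genes with the 7-base sequence ACGAGGA in their 3′ UTR (306 genes) fell with the hairpin on unnormalised values, to a mean log2 fold change of -0.023, -0.084, -0.130, -0.187 and -0.209 at 3, 6, 12, 24 and 48 h once 3′ UTR length, GC and CpG content were removed; at 24 h it ranked 2 from the lowest of 16321 sequences, TGCGGAC (167 genes, -0.209) ranked 3 and CGAGGAA, which overlaps the first, ranked 1. At 3 h ACGAGGA ranked 368 and TGCGGAC 10961 (0.005), and at 6 h they ranked 2 and 403 (-0.029 for TGCGGAC). ACGAGGA and TGCGGAC trace to 19 bases in the coding part of TWIST1 exon 1, GTCCGCAGTCTTACGAGGA (GRCh38 chromosome 7, 19117008 to 19117026, minus strand), which end in ACGAGGA and start with the reverse complement of TGCGGAC, so that a candidate explanation is seed pairing by the 2 strands of the hairpin, whose sequence is not in the sources used here. 3′ UTR length and base composition are argued against by the -0.187 left after their removal (-0.229 before), and a response to doxycycline or culture time in any cells by the mean of 0.071 ± 0.025 (SE) for the same site in SHEP-21N cells at 24 h, while loss of TWIST1 itself, the design's biological difference, was not tested and stays open. The search used lengths of 6, 7 and 8 bases, 2 sets of covariates and 5 times. At 3 h 2 of 2 lower genes, OAF and NOL10, held ACGAGGA, and 4.6% of genes not called held either site. Either site lay in 19 of 51 lower genes at 6 h (37.3%), 79 of 367 at 12 h (21.5%), 186 of 1455 at 24 h (12.8%) and 226 of 2265 at 48 h (10.0%), against 1.9% of higher genes at 24 h and 48 h. Of the 12 genes named as falls at 48 h, 3 hold a site in the 3′ UTR (4.6% of genes do), 10 in any part of a transcript (29.2% of 10630 do) and 6 share a run of 8 bases (32.5% do), searches widened in turn after the first was seen, on genes picked for their fall, which exclude nothing.

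The 12 h library numbered 2 of the hairpin experiment held RNA the other 17 lacked: 37 genes above 1 FPKM that stay under 0.2 elsewhere, against 1 to 6 such genes in each other library, among them OTX2 (9.64 FPKM), GAGE2D (14.7), PAGE1 (6.76) and RTN1 (5.17), beside MYC (9.69). A response to 12 h of hairpin expression is argued against by MYC at no more than 0.138 in the other libraries at 12 h. SHEP-21N RNA is argued against by its abundant genes, 31 of which reached a median of 0.111% of their SHEP-21N level where MYC would need 179%; 6 of these, such as MGST1 (2.05%) and MAGEA3 (1.30%), reached 1.11% or more, but ANXA1, at 816 FPKM in SHEP-21N cells, stood at 0.133 here (0.0163%). RNA of group 3 medulloblastoma cells may be a source but stays open: of 8 listed genes 2 met the test (IMPG2 at 2.10 and GABRA5 at 0.232 FPKM), while MAB21L2 (132) and NRL reach 139 and 1.51 in another library. No other biological explanation was tested.

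Each comparison of the hairpin with no doxycycline allows 10 splits of its 6 libraries, too few for a share under 0.05. The real split gave 4 genes at 3 h (highest other split 12), 4 at 6 h (7), 5 at 12 h (10), 69 at 24 h (5) and 10682 at 48 h (6888); 2, 3, 3, 1 and 1 of the 10 splits, the real one included, gave as many. Over any time 1 of 100 splits of the 18 libraries, the real one, gave as many as 10970, which argues against chance. The other 99 gave 2 to 10679 genes (median 134), so on the spike-in scale a grouping other than the real one came close. Why it did was not tested. On unnormalised values, a count chosen after seeing the data, the real grouping gave 3749 genes and the other 99 gave 0 to 3 (median 0).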
